A study of Mus musculus with 18 samples.

How the data were processed

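Total RNA was taken from 2 immortalized mouse embryonic fibroblast lines, WT and eIF2α S51A, per the labels' protocols. Polyadenylated RNA was made into strand-specific libraries and read from one end for 75 nt on an Illumina NextSeq 500. The submitters' processing notes name STAR, Cufflinks, Cuffdiff and the mouse genome mm10, with no version, order or role. The annotation used is not given in the sources used here. The 18 samples fall into 6 groups by genotype and time, from the sample labels.

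There are 3 tables, 1 for each time. Per the file headers, the authors' tables give log2 FPKM of each line, a log2 ratio and a q-value, so the replicates had been combined into 1 group value before deposit. In the deposited tables every entry has the status OK and is marked significant, and the highest q-value is 0.05, so genes not called are not seen. A log2 FPKM of -10 stands for a group listed at 0, which holds for 82, 112 and 78 genes in WT and 13, 10 and 32 genes in S51A at 0, 15 and 120 min. The deposited log2 ratio is S51A minus WT and equals the difference of the 2 columns within 0.01. A gene with a group at 0 therefore has an arbitrary ratio, and no fold is given for it. The top-ranked genes below include such genes because the ranking used the deposited ratio. Counts, library totals and sequencing depth were not used here, so the precision of a value is unknown and rests on the authors' q-value. One further numeric column in each table was not used. The table for 0 min has no symbol that starts with a digit, against 181 at 15 min and 149 at 120 min. Entries with 2 symbols, symbols turned into dates (11 at 15 min and 11 at 120 min) or repeated symbols were left out of gene lists and named genes, leaving 7549, 8289 and 6105 entries. Gene positions are those of the deposited tables in mm10, with 1 added to each start. Of genes matched by symbol to RefSeq on the same build, 47.8% at 0 min then had an identical start, against 4.01% without the addition.

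Every gene in a deposited table was taken as called, since its deposited q-value was at most 0.05. No test across samples could be made. Folds are the ratio of the authors' group FPKM values. Because p-values and uncalled genes were not used here, the planned test of list enrichment against uncalled genes was not run, and counts adjusted over the list alone cannot be given. In its place, chosen after seeing the files, the direction of called list members was set against that of the other called genes of the same table by a two-sided Fisher's exact test. All 30 lists were fixed before the data were examined. Lists with at least 5 called members were tested, giving 61 tests over 3 times, with Benjamini-Hochberg adjustment over all of them. These tests compare genes within a table, and genes are not independent replicates. On simulated directions for the genes of each table, lists of 40 genes with 85% higher were recovered in 98% of cases at 0 min (7555 genes), 98% at 15 min (8308 genes) and 97% at 120 min (6119 genes). Unchanged lists were called in 1.5%, 0.5% and 0.75% of cases. The simulated directions were drawn independently for each gene and adjusted over fewer tests. Most of the lists tested had fewer called members, and genes of a list or chromosome may move together. These rates therefore need not hold for the lists tested here.

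The median log2 ratio of each list was also placed among 10000 random lists of called genes matched on mean expression, as a description. At 0, 15 and 120 min the percentile was 100, 100 and 100 for interferon-stimulated genes, 99.9, 100 and 100 for NF-kB and cytokine genes, and 8.06, 0.365 and 0.320 for tRNA synthetases. It was 10.5, 32.4 and 0.0100 for the integrated stress response list, and 0, 23.1 and 79.1 for ribosomal proteins. For eIF2 and eEF2 control genes it was 45.6, 23.7 and 4.4, and for antioxidant enzymes 9.8, 33.6 and 60.2. Immediate early genes lay at 0, 0 and 100, and matrix genes at 100, 100 and 100. Because the tables hold no genes near a ratio of 0, the median of the listed genes with at least 1 FPKM (log2 -0.28, -0.21 and 0.41) falls at the edge of the gap between lower and higher calls and does not measure a shift of all genes.

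Time courses were computed as log2 of FPKM plus a pseudocount of 1 at 15 or 120 min over that at 0 min, centred on the median of the genes listed in both tables. The tables may have been normalized separately, so these values are descriptive. Such folds understate changes of low genes. The named genes followed a rule fixed before the data were examined. It took the 8 higher and 8 lower called genes with the largest log2 ratio among those with at least 5 FPKM in the higher group, up to 4 members by size of each list with at least 5 called members, and a fixed set of 13 genes. Across times it took 6 genes with opposite calls and the largest gap, and 6 per direction called at all times. For time courses it took the 8 highest and 8 lowest changes and up to 4 members of 4 stress lists. The text gives a part of these, and some are not reported here. Hoxc10 at 0 min lies outside this rule and was chosen after its values were seen.

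Alternatives were q under 0.01, a minimum fold of 2, at least 1 or 5 FPKM, other pseudocounts and centring. Leaving out replicates and blocking by replicate number were not possible with group values. Recomputing Benjamini-Hochberg values was not possible without the uncalled genes. Transcript lengths and GC content for the closing tests are medians over the GENCODE mouse transcripts of each symbol, found for 97.0% of genes listed at 0 and 120 min. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.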

Results

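The study measured polyadenylated RNA in 2 immortalized mouse embryonic fibroblast lines. One line was wild type (WT). The other carried the S51A form of eIF2α, in which the regulatory serine that stress kinases phosphorylate to slow translation initiation is replaced by alanine. Cells were untreated or were given 500 µM hydrogen peroxide, an oxidant, for 15 or 120 min. The labels list 3 samples for each of the 6 groups, 18 in all, while the series design text speaks of duplicates. The tables analysed here give 1 FPKM value (a fragment count scaled to transcript length and to mapped reads) per group and gene. The spread between samples, the number of samples behind a value and the sequencing depth are therefore unknown, and no standard deviation can be given. Each table lists genes that the authors called different between the lines at one time, with their q-value. Every statement that a gene was higher or lower in S51A rests on that call. Folds were computed from the authors' group values. A gene missing from a table was not called or not listed, and says nothing about equality. Nothing in the labels says that the samples came from separate cultures, so the authors' q-values may measure technical spread only. Each genotype is 1 line, so genotype and line cannot be separated.

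The first comparison asked how the lines differed before any oxidant. Eif2s1, which encodes eIF2α (chromosome 12, 78862072 to 78887010, mm10 coordinates of the gene), was lower in S51A, at 91.8 FPKM in WT and 45.3 FPKM in S51A, a 2.03-fold difference. This level does not check the labels, because a single amino acid substitution need not alter transcript level. Several targets of the transcription factor ATF4, the effector of eIF2α phosphorylation, were lower in untreated S51A cells. Chac1, a glutathione-degrading enzyme (chromosome 2, 119351242 to 119354327), was at 16.8 FPKM in WT and 4.41 FPKM in S51A. Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152337425 to 152344060), was at 9.65 FPKM in WT and 3.03 FPKM in S51A, and the asparagine synthetase gene Asns was at 111 FPKM in WT and 53.1 FPKM in S51A. Atf4 itself differed by only 1.27-fold, with 313 FPKM in WT and 246 FPKM in S51A. The authors' deposited table called 3749 genes higher and 3806 lower in S51A, and its q-values ran from 0.000118, which 4905 genes shared, up to the threshold of 0.05. Ddit3, Ppp1r15a and Eef2 were listed in no table. With a minimum fold of 2, 1667 genes were higher and 1132 lower.

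Genes for cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were lower in S51A for 18 of 19 called members (Fisher's exact test p = 7.55e-05, adjusted p = 6.56e-04). Their median ratio lay at percentile 8.06 of lists matched on expression, low but not extreme among such lists. Cars was at 73.0 FPKM in WT and 26.0 FPKM in S51A, and the exception was Eprs, at 37.8 FPKM in WT and 78.2 FPKM in S51A. The wider integrated stress response list was divided, with 11 called members higher and 17 lower (Fisher's exact test p = 0.344, adjusted p = 0.477). Its largest differences included Cbs, a transsulfuration enzyme, at 0.195 FPKM in WT and 1.01 FPKM in S51A. All 71 called cytosolic ribosomal protein genes were lower in S51A (Fisher's exact test p = 6.97e-22, adjusted p = 4.25e-20), among them Rps13, at 1333 FPKM in WT and 452 FPKM in S51A. Ribosomal protein genes have many processed pseudogenes, so their reads may have been shared with copies. Of the eIF2 and eEF2 control genes, 16 of 19 were lower (Fisher's exact test p = 0.00440, adjusted p = 0.0158). Their median ratio lay at percentile 45.6 of lists matched on expression, so it was not unusually low for genes of like expression. The direction test does not take expression into account. Eef2k, the kinase that phosphorylates elongation factor eEF2 (chromosome 7, 120842831 to 120907219), was at 4.14 FPKM in WT and 2.23 FPKM in S51A. Among the exceptions were the eIF2α kinase genes Eif2ak3, at 2.81 FPKM in WT and 12.2 FPKM in S51A, and Eif2ak2, at 10.8 FPKM in WT and 25.8 FPKM in S51A. Antioxidant enzyme genes were lower for 18 of 22 called members (Fisher's exact test p = 0.00431, adjusted p = 0.0158), such as Gpx1, a glutathione peroxidase, at 523 FPKM in WT and 152 FPKM in S51A. The thioredoxin-binding gene Txnip was on the other side, at 3.89 FPKM in WT and 29.7 FPKM in S51A. The median ratio of the antioxidant list lay at percentile 9.8 of lists matched on expression, also not extreme. Of the called targets of NRF2, the main transcription factor of the antioxidant response, 20 of 27 were lower (Fisher's exact test p = 0.0190, adjusted p = 0.0532), including the heme oxygenase gene Hmox1 at 234 FPKM in WT and 45.3 FPKM in S51A. That list did not pass the threshold, but did with directions permuted within chromosomes (permutation test, adjusted p = 0.00686).

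Of the lists tested, interferon-stimulated genes had the highest share of members higher in untreated S51A cells, with 33 of 34 called members higher (Fisher's exact test p = 1.56e-09, adjusted p = 2.51e-08). Psmb8, an immunoproteasome subunit, was at 0.268 FPKM in WT and 43.4 FPKM in S51A. Matrix and basement membrane genes were higher for 33 of 42 members (Fisher's exact test p = 1.49e-04, adjusted p = 8.91e-04), with the collagen gene Col1a2 at 155 FPKM in WT and 1098 FPKM in S51A. Mmp3, a matrix metalloproteinase, went the other way, at 104 FPKM in WT and 5.06 FPKM in S51A. NF-kB and cytokine genes were higher for 17 of 22 (Fisher's exact test p = 0.009996, adjusted p = 0.0321), such as the chemokine gene Cxcl5 at 0.490 FPKM in WT and 9.38 FPKM in S51A, whereas Ptgs2, a prostaglandin synthase, was at 142 FPKM in WT and 8.69 FPKM in S51A. Immediate early genes, which growth factors and stress induce within minutes, were lower for 32 of 49 (Fisher's exact test p = 0.0440, adjusted p = 0.0994). They included Fosl1 at 104 FPKM in WT and 8.69 FPKM in S51A, while Fos was higher, at 1.48 FPKM in WT and 14.8 FPKM in S51A. The immediate early list passed with a minimum fold of 2 (exact test, adjusted p = 0.00945) and with directions permuted within chromosomes (permutation test, adjusted p = 0.0217). The direction calls for antioxidant, eIF2 and eEF2 control, NF-kB and matrix genes did not pass with a minimum fold of 2, and the tRNA synthetase list then kept too few genes to test. Requiring 5 FPKM in either group also ended the call for eIF2 and eEF2 control genes.

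The largest single differences in untreated cells were genes absent or near absence in one line. Rhox12, a homeobox gene, was listed at 0 in WT and at 83.3 FPKM in S51A. The patterning genes Irx1, Pax8 and Zic1 were listed at 0 in WT and at 29.0, 11.2 and 9.45 FPKM in S51A. Grem1, a secreted antagonist of bone morphogenetic proteins, was lower in S51A, at 272 FPKM in WT and 1.78 FPKM in S51A.

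**Figure D1:**
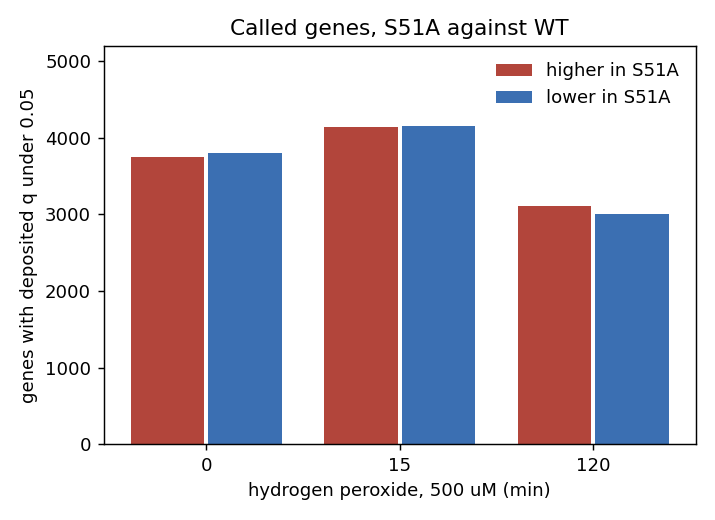
Number of genes (vertical axis) that the authors' deposited tables call higher (red) or lower (blue) in S51A than in WT, against minutes in 500 µM hydrogen peroxide (horizontal axis). The bars reach 3749 and 3806 at 0 min, 4147 and 4161 at 15 min, and 3113 and 3006 at 120 min.

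The second comparison set the lines side by side after 15 min of oxidant. Genes named in untreated cells again differed in the same direction, with Egr1 as an exception. Eif2s1 was at 90.5 FPKM in WT and 45.6 FPKM in S51A, Chac1 at 19.4 FPKM in WT and 3.68 FPKM in S51A, Trib3 at 9.06 FPKM in WT and 3.41 FPKM in S51A and Hmox1 at 234 FPKM in WT and 48.2 FPKM in S51A. Fos was higher in S51A, at 3.03 FPKM in WT and 8.06 FPKM in S51A. Egr1, an immediate early transcription factor gene (chromosome 18, 34861207 to 34864956), was lower in S51A here, at 26.5 FPKM in WT and 15.2 FPKM in S51A, having been higher at 0 min, at 23.3 FPKM in WT and 46.9 FPKM in S51A. The authors' deposited table called 4147 genes higher and 4161 lower. With a minimum fold of 2, these counts were 1680 and 1024.

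Aminoacyl-tRNA synthetase genes were lower for 17 of 18 called members after 15 min (Fisher's exact test p = 1.43e-04, adjusted p = 8.91e-04). So were 23 of 26 eIF2 and eEF2 control genes (Fisher's exact test p = 8.61e-05, adjusted p = 6.56e-04), including Eef2k at 4.59 FPKM in WT and 2.33 FPKM in S51A and the initiation factor gene Eif5 at 174 FPKM in WT and 79.3 FPKM in S51A. The median ratio of this control list lay at percentile 23.7 of lists matched on expression, so it was not unusually low for genes of like expression. Immediate early genes were lower for 35 of 51 (Fisher's exact test p = 0.0107, adjusted p = 0.0328), for example the phosphatase gene Dusp4 at 10.3 FPKM in WT and 0.616 FPKM in S51A. Ribosomal protein genes were lower for 49 of 55 (Fisher's exact test p = 1.64e-09, adjusted p = 2.51e-08). Their median ratio lay at percentile 23.1 of lists matched on expression, so it too was not unusually low for genes of like expression. Interferon-stimulated genes were higher for 31 of 32 (Fisher's exact test p = 6.94e-09, adjusted p = 8.47e-08), NF-kB and cytokine genes for 19 of 24 (Fisher's exact test p = 0.00393, adjusted p = 0.0158) and matrix genes for 30 of 42 (Fisher's exact test p = 0.00517, adjusted p = 0.0175). Antioxidant enzymes were divided, 7 higher and 13 lower (Fisher's exact test p = 0.263, adjusted p = 0.411), as were NRF2 targets, 9 higher and 18 lower (Fisher's exact test p = 0.122, adjusted p = 0.232), and integrated stress response genes, 11 higher and 17 lower (Fisher's exact test p = 0.344, adjusted p = 0.477). With a minimum fold of 2 the NF-kB and matrix calls did not pass, and ribosomal protein, tRNA synthetase and eIF2 and eEF2 control genes were too few to test. With at least 5 FPKM in either group the immediate early call did not pass.

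The third comparison, after 120 min, covered the later response. Genes of the integrated stress response were lower in S51A for 19 of 24 called members (Fisher's exact test p = 0.00351, adjusted p = 0.0158). Chac1 was at 17.6 FPKM in WT and 0.503 FPKM in S51A, a 35.0-fold difference, and Trib3 at 36.8 FPKM in WT and 3.36 FPKM in S51A. Sesn2, a leucine-sensing stress gene, was at 40.5 FPKM in WT and 2.77 FPKM in S51A, and the cystine transporter gene Slc7a11 was at 3.14 FPKM in WT and 0.232 FPKM in S51A. The members on the other side included Gdf15, a stress-induced cytokine gene, at 0.274 FPKM in WT and 7.06 FPKM in S51A, and Fgf21, listed at 0 in WT and at 0.859 FPKM in S51A. Eif2s1 was at 97.7 FPKM in WT and 57.7 FPKM in S51A and Eef2k at 3.71 FPKM in WT and 1.28 FPKM in S51A. Atf4 and Hmox1 were not listed at 120 min. Aminoacyl-tRNA synthetase genes were lower for 14 of 15 (Fisher's exact test p = 4.19e-04, adjusted p = 0.00213). Across 4200 genes, the change in the S51A to WT ratio from 0 to 120 min went with transcript length (Pearson r = -0.38), and these lists were not set against genes of like length.

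Inflammatory and immediate early genes were higher in S51A at 120 min. NF-kB and cytokine genes were higher for 22 of 25 called members (Fisher's exact test p = 1.61e-04, adjusted p = 8.91e-04). The interleukin gene Il6 was at 1.79 FPKM in WT and 56.5 FPKM in S51A, the chemokine gene Cxcl1 at 28.8 FPKM in WT and 666 FPKM in S51A, and Tnfaip3, a feedback inhibitor of NF-kB, at 2.23 FPKM in WT and 41.9 FPKM in S51A. Immediate early genes were higher for 32 of 44 (Fisher's exact test p = 0.00377, adjusted p = 0.0158), with Egr1 at 32.9 FPKM in WT and 304 FPKM in S51A, Fos at 3.81 FPKM in WT and 20.5 FPKM in S51A, and Cyr61, a matricellular growth regulator, at 27.5 FPKM in WT and 338 FPKM in S51A. Dusp4 stayed lower in S51A, at 9.65 FPKM in WT and 0.953 FPKM in S51A. Interferon-stimulated genes were higher for 29 of 30 (Fisher's exact test p = 6.10e-08, adjusted p = 6.20e-07). Ribosomal protein genes were higher for 48 of 49 (Fisher's exact test p = 2.03e-13, adjusted p = 6.21e-12), such as Rpl41 at 1428 FPKM in WT and 5078 FPKM in S51A. Their median ratio lay at percentile 79.1 of lists matched on expression. From 0 to 120 min, genes matched on length, GC content and expression shifted towards S51A by a median log2 ratio of 1.26, against 1.57 for ribosomal protein genes. That match was not close, since the matched genes were less expressed (largest gap 0.458 SD, against 0.25 allowed). The heat shock list was divided, 9 higher and 7 lower (Fisher's exact test p = 0.804, adjusted p = 0.908). Of its inducible chaperone genes, Hspa1b was at 7.31 FPKM in WT and 165 FPKM in S51A and Hspa1a at 0.289 FPKM in WT and 30.7 FPKM in S51A. Both were already higher in S51A at 0 min, with Hspa1b at 1.20 FPKM in WT and 12.3 FPKM in S51A and Hspa1a at 0.0467 FPKM in WT and 1.58 FPKM in S51A. These near-identical genes may share reads, so their separate levels are uncertain.

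At 120 min, eIF2 and eEF2 control genes were lower for 12 of 15 (Fisher's exact test p = 0.0192, adjusted p = 0.0532) and matrix genes higher for 24 of 35 (Fisher's exact test p = 0.0415, adjusted p = 0.0974), neither past the threshold. Antioxidant enzymes had 12 members higher and 6 lower (Fisher's exact test p = 0.239, adjusted p = 0.393), and NRF2 targets 10 and 11 (Fisher's exact test p = 0.829, adjusted p = 0.910). The authors' deposited table called 3113 genes higher and 3006 lower, or 1620 and 1277 with a minimum fold of 2. With that minimum the integrated stress response and immediate early calls did not pass, and tRNA synthetase genes were too few to test. The largest differences were again genes near absence in one line. Plac8 was at 1.22 FPKM in WT and 501 FPKM in S51A, Ogn, a small matrix proteoglycan gene, at 0.511 FPKM in WT and 152 FPKM in S51A, and Grem1 at 232 FPKM in WT and 1.08 FPKM in S51A.

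**Figure D2:**
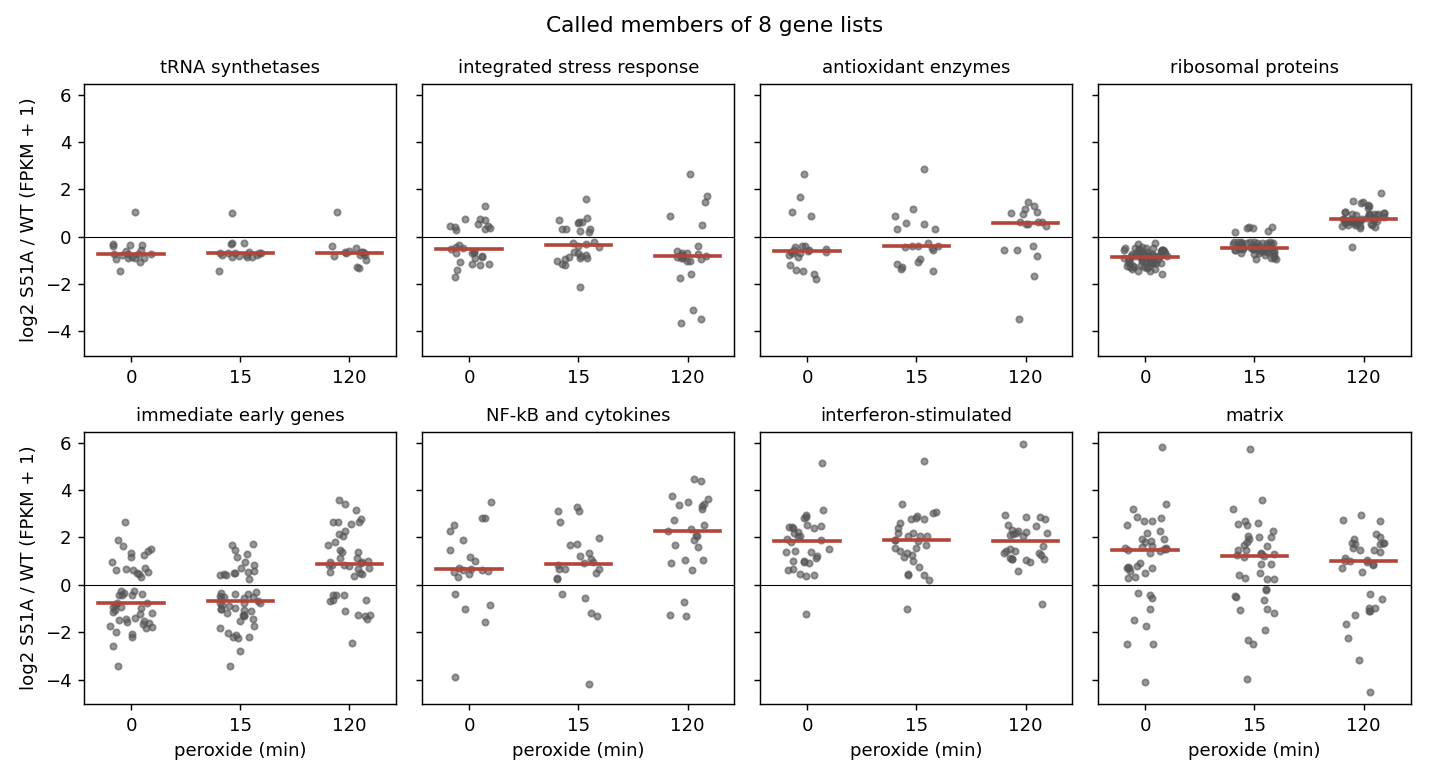
Log2 ratio of S51A to WT, from group FPKM plus 1 (vertical axis), for each called member (grey point) of 8 gene lists at 0, 15 and 120 min of peroxide (horizontal axis), with the median over called members as a red line. Points differ between times because each table lists its own called genes. The thin black line marks a log2 ratio of 0. Ribosomal protein genes lie below the black line at 0 min for all 71 called members and above it at 120 min for 48 of 49. Interferon-stimulated genes lie above the black line for 33 of 34, 31 of 32 and 29 of 30.

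Other lists showed no direction past the threshold at any time. Endoplasmic reticulum chaperone and unfolded protein response genes were higher for 12 of 15 at 0 min (Fisher's exact test p = 0.0203, adjusted p = 0.0537), 13 of 17 at 15 min (Fisher's exact test p = 0.0303, adjusted p = 0.0770) and 10 of 13 at 120 min (Fisher's exact test p = 0.0926, adjusted p = 0.188). Their splicing-activated factor gene Xbp1 was at 16.9 FPKM in WT and 45.9 FPKM in S51A before treatment. With at least 5 FPKM in either group, this list passed at 0 min (exact test, adjusted p = 0.0217) and 15 min (exact test, adjusted p = 0.0334). Cholesterol synthesis genes were higher for 11 of 14 (Fisher's exact test p = 0.0337, adjusted p = 0.0823), 12 of 16 (Fisher's exact test p = 0.0482, adjusted p = 0.105) and 8 of 13 (Fisher's exact test p = 0.581, adjusted p = 0.709). They too passed with that filter at 0 min (exact test, adjusted p = 0.0133) and 15 min (exact test, adjusted p = 0.0221). Targets of p53 were split 13 to 13, 14 to 13 and 14 to 8 between higher and lower (Fisher's exact tests p = 1, 0.8499 and 0.287, adjusted p = 1, 0.9096 and 0.438). The cyclin gene Ccnd1 was at 167 FPKM in WT and 13.6 FPKM in S51A at 0 min and the death receptor gene Fas at 2.87 FPKM in WT and 46.5 FPKM in S51A at 120 min. Cdkn1a was at 15.3 FPKM in WT and 10.9 FPKM in S51A at 0 min and was not listed at 120 min. S phase and mitosis genes were higher for 8 of 25, 9 of 25 and 8 of 20 (Fisher's exact tests p = 0.107, 0.229 and 0.375, adjusted p = 0.211, 0.388 and 0.498). Glycolysis and hypoxia genes were higher for 7 of 20, 9 of 21 and 9 of 16 (Fisher's exact tests p = 0.263, 0.663 and 0.804, adjusted p = 0.411, 0.793 and 0.908), and Vegfa was at 47.8 FPKM in WT and 9.32 FPKM in S51A at 0 min. Heat shock genes were higher for 7 of 18 at 0 min (Fisher's exact test p = 0.480, adjusted p = 0.610) and 7 of 21 at 15 min (Fisher's exact test p = 0.189, adjusted p = 0.349). Replication-dependent histone genes had 4, 5 and 4 called members, tested only at 15 min (Fisher's exact test p = 0.687, adjusted p = 0.805). No mitochondrially encoded gene was listed.

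The next question was whether the difference between the lines altered with time. Of 6369 genes listed at both 0 and 15 min, 98.1% differed in the same direction, against 81.9% of 4328 genes listed at 0 and 120 min and 94.9% of 4962 at 15 and 120 min. Fisher's exact test of direction at one time against the other gave odds ratios of 3622, 20.9 and 412, with p-values too small to be represented. Across genes without a group listed at 0, log2 ratios correlated with Pearson r = 0.969, 0.846 and 0.917 and Spearman rho = 0.947, 0.778 and 0.892. Genes are not independent replicates, and the tables hold called genes only, which raises the share with equal direction. A total of 3826 genes were listed at every time, of which 1718 were higher and 1767 lower throughout. Barx1 and Eya2 were listed at 0 in WT each time and at 8.17 and 5.70 FPKM in S51A at 120 min. Cd34, a progenitor surface protein gene, was at 0.295 FPKM in WT and 63.6 FPKM in S51A at 0 min and 0.230 FPKM in WT and 71.5 FPKM in S51A at 120 min. On the lower side, the phosphodiesterase gene Pde3b was at 10.9 FPKM in WT and 0.166 FPKM in S51A and 9.13 FPKM in WT and 0.146 FPKM in S51A at these times.

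Between 0 and 120 min, 784 genes were called in opposite directions, 449 from lower to higher in S51A and 335 from higher to lower. Only 15 of these had at least a 2-fold difference at both times. The genes with the largest gap between opposite calls included chemokine and immediate early genes. The chemokine gene Ccl2 (chromosome 11, 82035577 to 82037452) was at 419 FPKM in WT and 231 FPKM in S51A at 0 min and 242 FPKM in WT and 2436 FPKM in S51A at 120 min. Ier3, an immediate early gene, was at 149 FPKM in WT and 65.8 FPKM in S51A and then 86.2 FPKM in WT and 307 FPKM in S51A, and the long noncoding RNA Dancr at 10.8 FPKM in WT and 4.32 FPKM in S51A and then 8.57 FPKM in WT and 29.0 FPKM in S51A. Egr1, Cyr61 and the ErbB feedback inhibitor gene Errfi1 had their largest swings between 15 and 120 min. Errfi1 was at 93.7 FPKM in WT and 19.8 FPKM in S51A and then 23.4 FPKM in WT and 41.4 FPKM in S51A. These changes of direction are pairs of separate calls, and the change itself was not tested.

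The time course within each line was described for genes listed in both tables, with no test, since the values come from separate tables. Only genes called different between the lines at both times enter, so a line's whole response to the oxidant is not covered. Hmox1, for example, was left out at 120 min. After centring on the median of shared genes, 4 genes in WT and 5 in S51A of 6369 differed by 1 or more on the log2 scale (FPKM plus 1) between 0 and 15 min. With a pseudocount of 0.1 these were 30 and 8, so the order of the lines at 15 min depends on this choice. Between 0 and 120 min, 98 of 4328 genes did so in WT and 766 in S51A. With a pseudocount of 5, these were 38 and 434, and with 0.1 the count in WT was 196. Across 4200 genes with a known length, the change in S51A went with transcript length (Pearson r = -0.39 with log2 length, Spearman rho = -0.39), shorter transcripts having the more positive changes, against r = -0.04 and rho = -0.01 in WT. Genes are not independent replicates, and this trend was not removed from the counts. In WT, the values at 0 and 120 min were 1.55 and 15.3 FPKM for the stress transcription factor gene Atf3, 8.69 and 40.5 for Sesn2, and 9.65 and 36.8 for Trib3. In S51A, Sesn2 stood at 4.38 and 2.77 FPKM and Trib3 at 3.03 and 3.36, while Atf3 stood at 3.18 and 44.6. Over the 18 shared members of the integrated stress response list, the median centred log2 change was 0.28 in WT and 0.20 in S51A, with 4 at least 1 higher and 0 at least 1 lower in WT, and 2 and 3 in S51A. Hspg2, a basement membrane proteoglycan gene, stood at 0.642 and 10.9 FPKM in WT.

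Changes from 0 to 120 min were ranked over genes called different between the lines at both times. Among the 8 largest positive changes in S51A were those of Il6, at 2.64 FPKM at 0 min and 56.5 at 120 min, Hspa1b, at 12.3 and 165, Hspa1a, at 1.58 and 30.7, and Ccl2, at 231 and 2436. Il6 in WT stood at 1.49 and 1.79 FPKM. Junb, an immediate early gene, stood at 91.1 and 556 FPKM in S51A and at 64.0 and 88.6 in WT. Among the most negative changes in S51A were Gas1, a growth arrest gene, at 76.6 and 11.5 FPKM, and the transcription factor gene Foxc1, at 54.6 and 8.11. Foxc1 in WT stood at 20.8 and 4.20 FPKM. The most negative in WT was Cyr61, at 206 and 27.5 FPKM, against 263 and 338 in S51A. Of the immediate early list, 19 of 39 shared members were at least 1 higher on the centred log2 scale at 120 min in S51A and 4 in WT, while 3 in S51A and 8 in WT were at least 1 lower. For ribosomal proteins 45 of 46 were at least 1 higher in S51A and 0 in WT. Between these times their S51A to WT log2 ratio (FPKM plus 1) shifted by a median of 1.57, against 1.26 for other genes matched on length, GC content and expression, which were less expressed. For p53 targets 6 of 18 in S51A and 1 in WT were at least 1 higher and 0 at least 1 lower in either line. Pmaip1, an apoptosis gene, was at 6.82 and 17.6 FPKM in S51A and 0.607 and 1.79 in WT. It was higher at 120 min in both lines, and the pseudocount of 1 understates its change most in WT, where its values were low. For NRF2 targets 3 of 18 in S51A and 1 in WT were at least 1 higher and 0 at least 1 lower in either line, with the thioredoxin gene Txn1 at 431 and 1389 FPKM in S51A. The length trend in S51A was not removed from the counts of these lists.

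**Figure D3:**
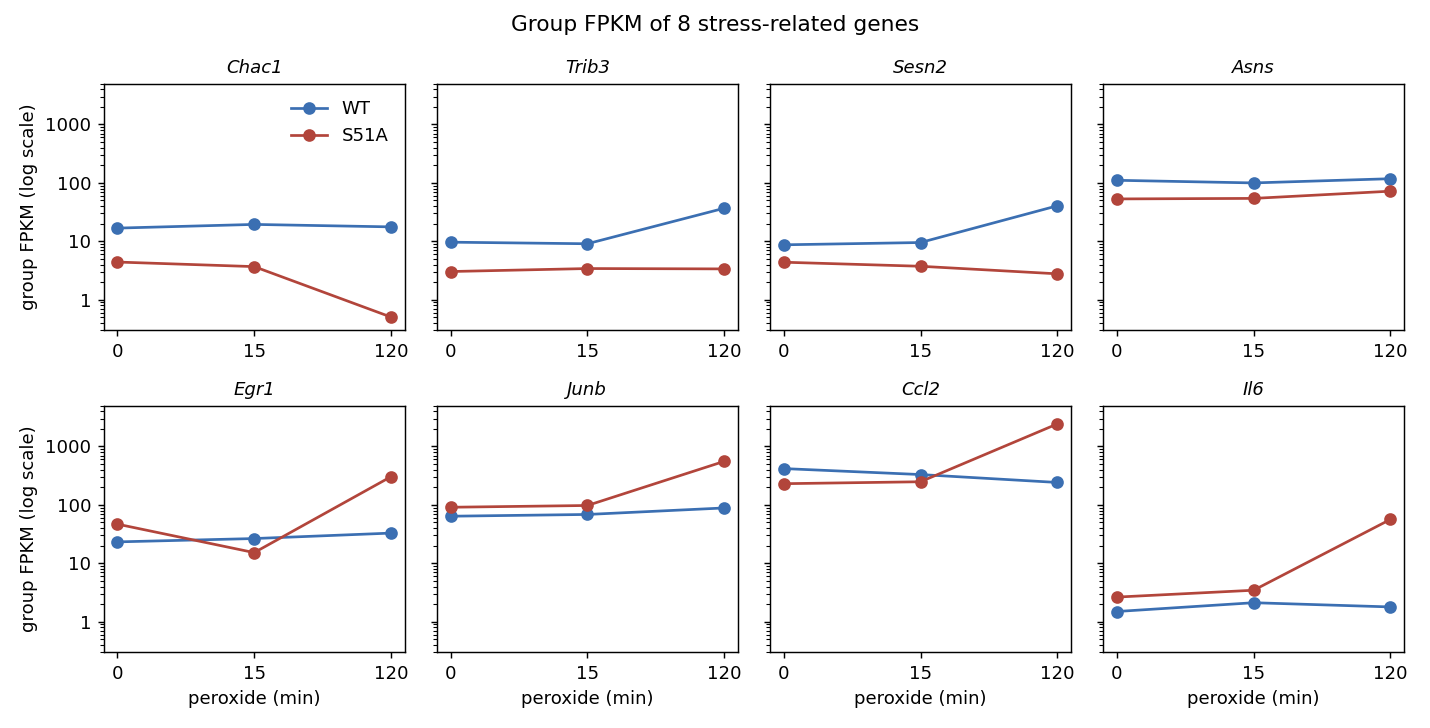
Group FPKM on a log scale (vertical axis) of 8 stress-related genes at 0, 15 and 120 min of peroxide (horizontal axis, categories) in WT (blue) and S51A (red). The genes are a selection from those named in the text. At 120 min, 5 of 24 called integrated stress response genes were higher in S51A, among them Atf3 and Gdf15, and none of these is shown. Each point is the authors' single group value, without error, and lines join times. Trib3 and Sesn2 stand highest in WT at 120 min, at 36.8 and 40.5 FPKM, whereas Il6, Ccl2, Junb and Egr1 stand highest in S51A at 120 min.

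Markers of other cell types gave no group of 3 or more genes at 5 FPKM or above in one line only. Of the fibroblast list, 6 of 9 called members were higher in S51A at 0 min (Fisher's exact test p = 0.340, adjusted p = 0.477), 6 of 9 at 15 min and 5 of 7 at 120 min, and Dcn, a proteoglycan gene, was on the lower side, at 54.2 FPKM in WT and 8.88 FPKM in S51A at 0 min. Smooth muscle and myofibroblast markers were higher for 4 of 5, 6 of 7 and 5 of 6 at the 3 times (Fisher's exact tests p = 0.215, 0.0695 and 0.219, adjusted p = 0.382, 0.146 and 0.382). Acta2, smooth muscle actin, was at 23.6 FPKM in WT and 111 FPKM in S51A at 0 min. Neural and glial markers had 7, 5 and 3 called members, of which 3, 2 and 1 were higher, and adipocyte markers 5, 3 and 4, of which 1, 2 and 2 were higher. The called members numbered 3, 2 and 1 for macrophage, 3, 4 and 3 for cartilage and bone, 2 each time for endothelial, 1 each time for epithelial and for skeletal muscle, and 0 for stem cell markers.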

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

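The tests of a single scaling factor, of the lines' own response and, for ribosomal proteins, of a length trend were chosen after the result was seen, as was the limit on how far matched genes may differ. The calls at 2 times differ in direction for 118 genes between 0 and 15 min, 784 between 0 and 120 min and 254 between 15 and 120 min. The difference between times was not tested, since the tables hold no error for a group value. By list, 45 of 46 ribosomal protein genes listed at 0 and 120 min changed sides, as did 14 of 39 immediate early genes and 5 of 11 antioxidant enzyme genes. The change in S51A from 0 to 120 min went with transcript length across genes (Pearson r = -0.39), and the antioxidant genes were not set against genes of like length.

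Ribosomal protein genes were lower in S51A at 0 min and higher at 120 min. Their S51A to WT log2 ratio (FPKM plus 1) shifted by a median of 1.57 between these times, while the other genes shifted by -0.058, which argues against one scaling factor between the tables, as the lower quartile of the ribosomal genes lay at 1.38. From 0 to 120 min the median log2 change was 1.59 in S51A and -0.010 in WT before centring, and 1.77 and 0.09 after centring, while from 0 to 15 min the centred medians were 0.19 in S51A and -0.35 in WT, over 52 genes. In S51A the change also followed transcript length (Pearson r = -0.39 across 4200 genes, -0.04 in WT), and genes matched on length, GC content and expression shifted by a median of 1.26 (highest of 10000 sets 1.61, with 99.97% of sets below the ribosomal median). A length or expression trend of the S51A libraries at 120 min could thus account for most of the shift, and it cannot be excluded as the whole cause, since the matched genes were less expressed (log2 8.99 against 9.91), nor can it be told apart from a response of the line with 1 line per genotype.

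NF-kB, cytokine and immediate early genes shifted towards S51A at 120 min, with a median shift of the log2 ratio of 1.11 over 56 genes with a known length. Genes matched on length, GC content and expression shifted by 0.0131 (highest of 10000 sets 0.356), and the other genes by -0.059 against a lower quartile of 0.393. Neither a length trend as seen in the matched genes nor one scaling factor is thus large enough for the median shift. These lists were taken for a closer look because of their own results, so their rank among matched sets is no test of the shift itself. The median change before centring was 0.687 in S51A and -0.30 in WT. After centring, it was 0.87 in S51A and -0.20 in WT for immediate early genes, and 0.86 and -0.21 for NF-kB and cytokine genes. A stronger or longer inflammatory response of S51A cells to the oxidant is a hypothesis that may be tested in further lines. It cannot be told apart from other differences between these 2 lines, or from a property of 1 set of cultures.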

How the results depend on the processing

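Of the alternatives below, centring for the gene lists, permutation within chromosomes and the pseudocount for correlations were chosen after seeing the data. No paired analysis was possible because the tables give 1 value per group and no replicate numbers. Leaving out replicates, blocking and count-based tools were not run for the same reason. Benjamini-Hochberg values were not recomputed because genes not called are not seen, so the filters on FPKM kept the deposited q-values. Depth is unknown and its limits could not be assessed. Counts of higher and lower calls stayed within 1.5 times under q under 0.01, both FPKM filters and centring. With a minimum fold of 2 they were 1667 and 1132 at 0 min, 1680 and 1024 at 15 min, and 1620 and 1277 at 120 min. With a pseudocount of 1 and that minimum they were 1117 and 888, 1160 and 773, and 1182 and 857. The minimum removes genes, and the pseudocount lowers the folds of low genes. Opposite calls at 0 and 15, 0 and 120, and 15 and 120 min numbered 42, 419 and 107 with q under 0.01 at both times, and 1, 15 and 2 with a minimum fold of 2 at both times, so most opposite calls were under 2-fold at one or both times. Lists with a direction call fell to 3, 2 and 3 at 0, 15 and 120 min with a minimum fold of 2, which leaves fewer genes. For the time course at 15 min, WT counts were 30, 1 and 2 and S51A counts 8, 3 and 3 with a pseudocount of 0.1, with a pseudocount of 5 and with at least 5 FPKM. At 120 min WT counts were 196 and 38 with pseudocounts of 0.1 and 5, and the S51A count was 434 with a pseudocount of 5. A smaller pseudocount admits low genes by construction. With directions permuted within chromosomes, NRF2 targets (permutation test, adjusted p = 0.00686) and immediate early genes (permutation test, adjusted p = 0.0217) also passed at 0 min, as did immediate early genes with a minimum fold of 2. Centring changed the direction of other genes and left the share of NRF2 targets as it was (exact test, adjusted p = 0.0357), so it was not used to judge that list. No named gene or called list changed direction under an alternative that gave it a value. For named genes only centring could have done so, since the other alternatives keep the sign of the ratio. Of 306 named values, 22 did not reach q under 0.01 and 25 lay under a 2-fold difference, or 46 with a pseudocount of 1.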

Other observations

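Hox genes differed between the lines in both directions. In untreated cells Hoxd9, Hoxd10, Hoxd11 and Hoxa11 were listed at 0 in WT and at 2.20, 2.95, 1.16 and 2.33 FPKM in S51A. Hoxc10 was on the other side, at 26.5 FPKM in WT and 1.55 FPKM in S51A, and stayed so at 120 min, at 24.6 FPKM in WT and 1.40 FPKM in S51A. The list as a whole had no direction, with 12 of 23 higher at 0 min (Fisher's exact test p = 0.837, adjusted p = 0.910), 14 of 25 at 15 min and 8 of 15 at 120 min. Of the X- and Y-linked marker genes, Xist was listed at 120 min, at 0.0367 FPKM in WT and 12.4 FPKM in S51A, and no Y-linked gene was listed. Both were read from single group values.

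The share of called genes that were higher in S51A differed by chromosome, a pattern noticed in the data and then tested on them. At 0 min it ran from 29.0% on chromosome 9 to 75.6% on chromosome 19, and at 120 min from 24.4% to 81.3% on these chromosomes. The SD over 20 chromosomes was 15.0 percentage points at 0 min, 16.5 at 15 min and 17.3 at 120 min. Shares in the proximal and distal parts of a chromosome, split at the median position of its called genes, were compared over the 20 chromosomes in 6 tests. Pearson r was 0.757 at 0 min (permutation p = 0.00016, adjusted p = 0.00024), 0.816 at 15 min (permutation p = 3e-05, adjusted p = 6e-05) and 0.845 at 120 min (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 6e-05). Spearman rho was 0.669, 0.701 and 0.820 (permutation p = 0.00155, 0.0008 and 3e-05, adjusted p = 0.00155, 0.00096 and 6e-05). Without the 2 chromosomes farthest from the median, r was 0.724, 0.757 and 0.803.

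With directions permuted among genes of like length, GC content and expression, the highest SDs of 10000 permutations were 5.495, 4.87 and 6.01, which argues against the make-up of the chromosomes as the cause. The correlation of the proximal and distal parts (r = 0.757 at 0 min) makes small local clusters of genes an unlikely cause. A difference in chromosome number between the 2 immortalized lines may contribute, and would weigh most on small differences. The SD with counting noise removed was 14.4 points among genes with under 2-fold difference and 9.56 among those with over 4-fold difference at 0 min. It was 16.7 and 10.5 points at 15 min, and 16.9 and 12.8 at 120 min. Intervals were computed only for the difference between the unadjusted SDs. They included 0 at 0 min (-1.76 to 5.08), 15 min (-0.23 to 6.50) and 120 min (-2.04 to 5.34). The unadjusted SDs hold more counting noise in the smaller group over 4-fold, so these intervals cannot decide on the gap with noise removed. Chromosome number therefore stays open, and genotype and line of origin cannot be separated.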
